A study of Mus musculus with 6 samples.

How the data were processed

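Per the labels' protocols, total RNA of mouse brain was depleted of ribosomal RNA, made into libraries with the NEBNext Ultra RNA kit and sequenced as read pairs on an Illumina HiSeq instrument. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. The expression table holds raw counts and RPKM values for 6 libraries. The deposited counts are whole numbers per row, unnormalised. The deposited RPKM values equal the count per kilobase of row length and per 1e6 counts of the column total in 100% of values (relative tolerance 0.001). The deposited table of the authors' comparison holds mean RPKM per group, a log2 fold change, which equals the log2 ratio of the means, and p-values and q-values, where the q-values of the authors equal a Benjamini-Hochberg adjustment of their p-values. The authors' test is not given in the sources used here. Row length, another deposited value, was used as given.

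The table has 56826 rows, of which 23473 carry a gene symbol and 33353 (58.7%) the name of a FANTOM3 cDNA clone. Clone rows overlapped the span of a gene row, introns included, on the same strand in 66.3% of cases (bedtools 2.31.1, at least 1 base). Counts identical to another row at the same position were found for 1896 rows, so some reads were counted in more than 1 row. Of 22977 gene IDs in the file, 22897 matched the RefSeq table, which gave the biotype of 20160 protein-coding and 1622 lncRNA rows. Of 344 gene list members 326 matched a row, 5 of them by gene ID. The list of mitochondrially encoded genes had no matched member and was not tested. The 12 gene names altered to dates were left as deposited.

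Counts were tested with edgeR 4.0.16 (R 4.3.3), using TMM factors, filterByExpr defaults and the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over 40170 rows and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. The biological coefficient of variation was 17.4% over all libraries, 13.4% in sham and 20.5% in ischemia/reperfusion. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 26 lists. A floor of 3 counts corresponded to 0.0604 to 0.0660 CPM per library and covers counting error only. Replicates differed by more than sampling noise, so each library was counted as 1 sample.

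The groups, the gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were up to 10 higher and 10 lower symbol genes past the threshold with at least 1 CPM and groups that did not overlap, up to 4 members of each list with the smallest p, and up to 5 higher and 5 lower lncRNA genes past the threshold with at least 0.5 CPM; where none passed, the 5 smallest p-values were named. List members that passed over the list alone, the called clone row and Rian were also named, after their values were seen. Alternatives were RLE and upper-quartile factors, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, camera with an estimated correlation and fry. A fit on gene rows alone and edgeR without robust estimation were added after seeing the data.

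The tests were tested on simulated data with the means, library sizes and dispersions of this comparison, 40170 rows and 200 changed rows. Changed rows had a mean of at least 1 CPM, each row had 1 dispersion for both groups, and rows were drawn independently. The recovered shares therefore do not cover rows under 1 CPM or groups of unequal spread, as here. With gene-wise dispersions edgeR recovered 77% of 100 rows changed 2-fold and 100% of 100 changed 4-fold, and DESeq2 92% and 100%. Of all calls 11.4% were unchanged rows with edgeR and 18.2% with DESeq2, above the nominal 5%. With trended dispersions, which vary less between rows, these shares were 5.37% and 9.30%. A simulated list of 20 rows shifted by 0.7 on the log2 scale was called by camera with the preset and with the estimated correlation. Its rows were drawn independently, so it cannot show which setting suits lists whose members are correlated.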

Results

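Total RNA from mouse brain was sequenced after removal of ribosomal RNA in 2 groups of 3 libraries. One group had a sham operation. The other had transient occlusion of the middle cerebral artery, a model of ischemic stroke, with 1 h of ischemia followed by 6 h of reperfusion. The comparison asks which long noncoding RNAs (lncRNAs) and messenger RNAs differ in abundance after ischemia and reperfusion. The deposited counts per library, in units of 1e6, were 48.9 ± 0.778 in sham (SD, n = 3) and 46.7 ± 1.65 in ischemia/reperfusion (SD, n = 3), and ranged from 45.4 to 49.7. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

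After ischemia and reperfusion, heat shock, immediate early and cytokine genes had the 3 smallest p-values among the gene groups tested (camera with a preset correlation). This order holds only there. No list was called with an estimated correlation, where astrocyte markers had the smallest unadjusted p (0.0465) and also the smallest in fry's directional test (0.00799). Hspa1a and Hspa1b, which encode the inducible Hsp70 chaperones, averaged 21.6 ± 7.04 and 17.5 ± 4.30 CPM (counts scaled to a library total of 1e6) in sham and 428 ± 212 and 388 ± 216 CPM in ischemia/reperfusion (SD, n = 3 each). No gene-symbol row passed an adjusted p of 0.05 over all rows tested (edgeR quasi-likelihood test, Benjamini-Hochberg), and Hspa1b had an adjusted p of 0.150. Of 40170 rows tested, 1 was called higher and 0 lower. At an unadjusted p under 0.05 there were 3508 higher and 2773 lower rows, where 2008.5 rows in all are expected by chance. Gene rows had 1064 higher and 1449 lower, and clone rows, some of which count reads of a gene row again, 2444 and 1324. Clone rows overlapping a gene row on the same strand had a median log2 fold change of 0.11, against −0.04 for gene rows. The total of 6281 was 3814 without sham replicate 1 and 8628 without ischemia/reperfusion replicate 1, the extremes of leaving out 1 library. Among rows tested, 21.6% had groups that did not overlap, against 10% by chance.

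The number of calls depended on the libraries and the tool. It was 1057 without ischemia/reperfusion replicate 1, 43 without ischemia/reperfusion replicate 2 and 34 without sham replicate 2, and 0 without any of the other 3 libraries. DESeq2 called 584 rows, limma-voom 4 and edgeR with no low-count filter 77. DESeq2 gave no adjusted p for 7793 of the 40170 rows, so its calls here and below come from an adjustment over fewer rows than those of edgeR.

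The row that passed was the cDNA clone row fantom3_5330411G14 on chromosome 12 from 109737780 to 109741503 (mm10), inside the gene Mirg. It rose from 6.05 ± 0.675 to 15.9 ± 2.63 CPM (SD, n = 3 each), a log2 fold change of 1.39 ± 0.15 (SE) with an adjusted p of 0.0423 (edgeR). It was higher in 3 of 3 ischemia/reperfusion libraries than in every sham library. This call was lost without sham replicate 1 (edgeR adjusted p = 0.491), without sham replicate 3 (0.213), without ischemia/reperfusion replicate 3 (0.124) and when rows needed a mean of at least 1 CPM (0.0802). The gene-symbol rows with the 5 smallest p-values in edgeR were Rtl1, Oprl1, Mirg, Ryr3 and Adamts19, none of them past the edgeR threshold. DESeq2 called all 5, with adjusted p from 5.1e-08 for Rtl1 to 0.00011 for Ryr3. Rtl1, a retrotransposon-derived gene, had a log2 fold change of 0.97 ± 0.12 (SE) and an edgeR adjusted p of 0.0751. Its row spans the lncRNA gene 6430411K18Rik on the other strand, so reads of that gene may be included. Oprl1, the nociceptin receptor, had 127 ± 3.62 CPM in sham and 83.2 ± 2.69 CPM in ischemia/reperfusion (SD, n = 3 each). Ryr3, an intracellular calcium release channel, had 47.2 ± 2.71 and 76.5 ± 8.17 CPM. Adamts19 had 1.04 ± 0.207 and 3.30 ± 0.870 CPM.

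**Figure D1:**
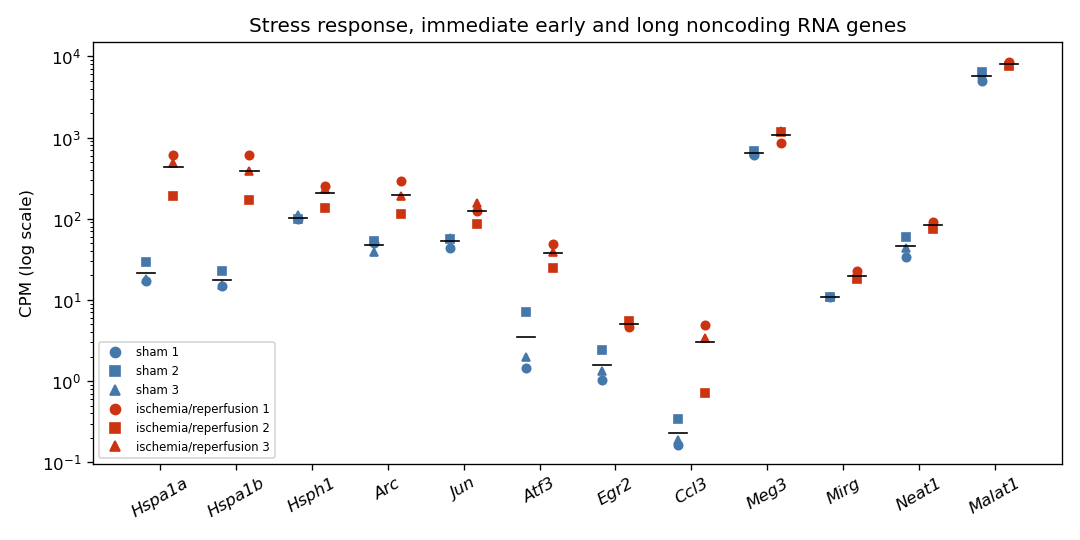
CPM on a log axis for 12 genes in each library, with sham in blue, ischemia/reperfusion in red, the replicate number as the marker shape and the group mean as a black bar. For Hspa1a the means were 21.6 and 428 CPM, and for Meg3 they were 644 and 1075 CPM.

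Immediate early genes, which neurons and glia transcribe within minutes of stimulation, rose as a group. Of 22 members, 21 had a positive log2 fold change, with a median of 0.88 (camera with a preset correlation of 0.01, adjusted p = 1.6e-07). The call was lost with an estimated correlation, which was 0.50 in this list, where adjusted p = 0.780. With edgeR none of the members passed over all rows, and 4 passed when adjusted over the list alone, Jun, Egr2, Arc and Atf3. DESeq2, over the rows it adjusted, called the same 4 genes, with adjusted p from 1.3e-06 for Jun to 0.00146 for Atf3. Arc, a regulator of synaptic strength, had 47.2 ± 7.21 CPM in sham and 198 ± 87.1 CPM in ischemia/reperfusion (SD, n = 3 each). Atf3, a stress-induced transcription factor, had 3.47 ± 3.07 and 37.4 ± 12.1 CPM. Its log2 fold change was 3.43 and, without sham replicate 2, 4.45 with an edgeR adjusted p of 0.0282. Sham replicate 2 stood apart, with a mean score of 0.76 above the sham mean on the log2 scale, against −0.30 and −0.45 in the other sham libraries and 0.84 to 1.40 in ischemia/reperfusion.

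Heat shock and chaperone genes rose as a group, with 14 of 14 members positive and a median log2 fold change of 0.48 (camera, adjusted p = 3.0e-06). This call was lost with an estimated correlation (adjusted p = 0.780). With edgeR 7 of these passed when adjusted over the list alone, Hspa1a, Hspa1b, Chordc1, Hsph1, Bag3, Hspb1 and Dnajb1, and 0 over all rows. DESeq2, over the rows it adjusted, called all of these but Dnajb1, among them Hspa1b (adjusted p = 6.4e-14) and Hspa1a (8.0e-14). Beside Hspa1a and Hspa1b, Hsph1, a partner of Hsp70, had 103 ± 6.17 CPM in sham and 207 ± 64.1 CPM in ischemia/reperfusion (SD, n = 3 each). Hspa1a and Hspa1b are near-identical copies, so the division of reads between them is uncertain. The smallest of the 3 ischemia/reperfusion scores, 0.68, was that of replicate 2.

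Cytokine and chemokine genes rose as a group, with 17 of 17 members positive and a median log2 fold change of 1.93 (camera, adjusted p = 2.8e-09), and adjusted p = 0.780 with an estimated correlation. With edgeR 7 passed when adjusted over the list alone, which were Il1rn, Lif, Csf1, Ccl3, Ccl4, Cxcl2 and Cxcl10, and 0 over all rows. DESeq2, over the rows it adjusted, called 4, Ccl3, Csf1, Lif and Ccl4, with adjusted p from 0.00303 to 0.0204. The log2 fold change of Cxcl10 was 2.77 and, without sham replicate 2, 5.11. Its counts in replicates 1, 2 and 3 were 0, 8 and 1 in sham and 15, 20 and 28 in ischemia/reperfusion. The 5.11 thus rests on 1 count in sham. Counts of Il1rn were 0, 4 and 4 in sham and 31, 11 and 13 in ischemia/reperfusion. Csf1, a growth factor of microglia and macrophages, had 15.0 ± 0.852 CPM in sham and 21.3 ± 0.813 CPM in ischemia/reperfusion (SD, n = 3 each). Ccl3, a chemokine, had 0.231 ± 0.0979 and 3.01 ± 2.11 CPM. Sham replicate 2 had a score of 1.50, against −0.84 and −0.65 in the other sham libraries and 1.98 to 2.79 in ischemia/reperfusion.

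Genes of the unfolded protein and integrated stress responses rose as a group, with 11 of 14 members positive and a median log2 fold change of 0.37 (camera, adjusted p = 0.0151). With an estimated correlation adjusted p = 0.860. The call was also lost without sham replicate 1 (camera, adjusted p = 0.0914), sham replicate 3 (0.120) or ischemia/reperfusion replicate 1 (0.219). Scores were 0.74, 0.07 and 0.39 in ischemia/reperfusion replicates 1, 2 and 3, and −0.10 to 0.18 in sham, so that ischemia/reperfusion replicate 2 lay below sham replicate 2. Ppp1r15a, which restores translation after stress, was the 1 member that passed when adjusted over the list alone (edgeR), and the 1 that DESeq2 called over the rows it adjusted, at 16.3 ± 4.30 CPM in sham and 35.0 ± 10.0 CPM in ischemia/reperfusion (SD, n = 3 each).

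Neutrophil and monocyte markers rose as a group, with 7 of 7 tested members positive and a median log2 fold change of 1.03 (camera, adjusted p = 0.00308). The list had 13 members, of which 12 matched a row and only 7 passed the low-count filter. With an estimated correlation adjusted p = 0.780. With edgeR 4 passed when adjusted over the list alone, S100a8, S100a9, Mmp8 and Csf3r, and DESeq2 called 2 over the rows it adjusted, S100a8 and S100a9. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, had 1.64 ± 0.580 and 2.04 ± 0.616 CPM in sham and 3.55 ± 0.818 and 4.87 ± 1.77 CPM in ischemia/reperfusion (SD, n = 3 each). Scores of the list were −0.62 to 0.42 in sham and 0.47 to 1.14 in ischemia/reperfusion. Erythroid and blood markers, not called, were positive in 5 of 5 tested members. Of these, Hba-a1 and Hba-a2 have almost the same positions and near-equal counts (2916 and 2946 in sham replicate 1), so the 2 are not independent members. Both lists scored lowest in sham replicate 3 (−0.62 and −0.39) and highest in ischemia/reperfusion replicate 2 (1.14 and 0.67). In the other libraries the 2 scores ranked differently. They were 0.19 and 0.45 in sham replicate 1 and 0.42 and −0.06 in sham replicate 2. In ischemia/reperfusion replicate 1 they were 0.47 and 0.11, and in replicate 3 0.90 and −0.02. A difference in the blood left in the tissue is not excluded.

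Astrocyte markers fell as a group, with 8 of 10 members negative and a median log2 fold change of −0.24 (camera, adjusted p = 0.00751), and adjusted p = 0.780 with an estimated correlation. The members that passed with edgeR when adjusted over the list alone were Gjb6, Aldoc and Glul, and DESeq2 called Gjb6 over the rows it adjusted (adjusted p = 0.00318). Gjb6, the gap junction protein connexin 30, had 109 ± 5.02 CPM in sham and 70.3 ± 13.2 CPM in ischemia/reperfusion (SD, n = 3 each). Glul, glutamine synthetase, had 1882 ± 129 and 1492 ± 138 CPM. Genes of reactive astrocytes were not called (camera, adjusted p = 0.339).

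Camera with the preset correlation called 6 of 26 lists between the 2 conditions, and 15 lists in the highest of the other divisions of the same 6 libraries into 3 and 3. Of the 10 divisions, the real one included, 8 called at least 6 lists, so the number of lists called does not set the conditions apart. The estimated correlation was 0.49 to 0.67 in the 5 lists called higher and 0.04 in astrocyte markers, against the preset 0.01. With an estimated correlation 0 lists were called, and with fry's directional test 0. Fry's mixed test, which asks whether members change in either direction, called 3 lists, those of lncRNAs (adjusted p = 0.00411), interferon response genes (0.0244) and heat shock genes (0.0373).

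**Figure D2:**
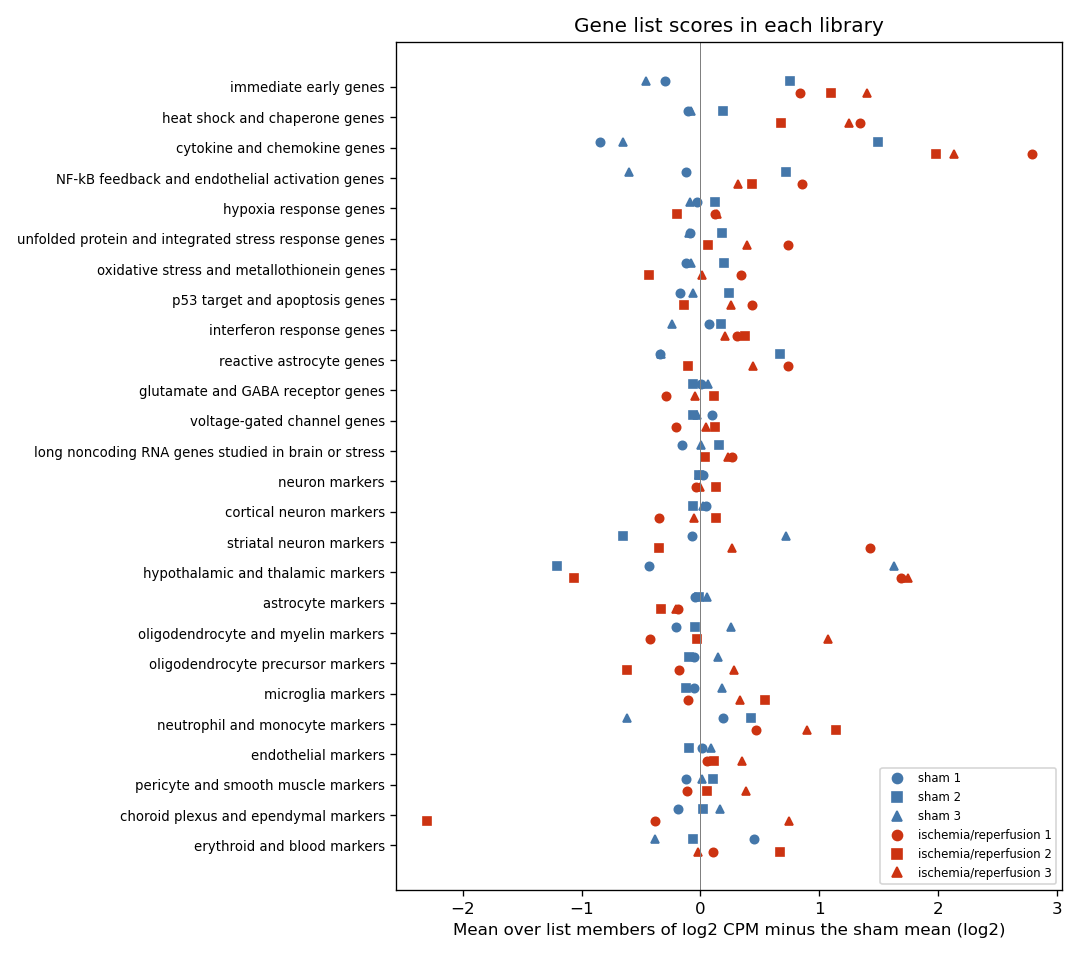
Mean over list members of log2 CPM minus the sham mean, in log2 units, for each of 26 gene lists and 6 libraries, with sham in blue, ischemia/reperfusion in red and the replicate number as the marker shape. Heat shock scores were 0.68 to 1.34 in ischemia/reperfusion and −0.11 to 0.19 in sham.

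The other lists were not called. The NF-kB feedback list had an adjusted p of 0.0775 (camera) and a median log2 fold change of 0.36, with 12 of 14 members positive. When adjusted over the list alone (edgeR) 1 passed in each direction. Nfkbiz, a regulator of NF-kB, had 6.77 ± 2.19 CPM in sham and 10.98 ± 1.45 CPM in ischemia/reperfusion (SD, n = 3 each), and Vcam1, an adhesion molecule of endothelium, had 28.8 ± 4.30 and 19.3 ± 1.52 CPM. DESeq2, over the rows it adjusted, called Vcam1 (adjusted p = 0.0134). Microglia markers had an adjusted p of 0.208 (camera), and Cx3cr1, the fractalkine receptor, had 9.88 ± 2.91 and 21.6 ± 5.76 CPM. DESeq2 also called Cx3cr1 (adjusted p = 0.00069), Sall1 of the same list (0.0104), the interferon response gene Rsad2 (0.0373) and, lower, the oligodendrocyte precursor marker Pdgfra (0.0252). With edgeR all of these but Pdgfra passed when adjusted over the list alone. Interferon response genes had an adjusted p of 0.234, oligodendrocyte precursor markers 0.364, endothelial markers 0.380, erythroid and blood markers 0.380, oxidative stress and metallothionein genes 0.438, hypoxia response genes 0.509, pericyte and smooth muscle markers 0.515 and p53 target and apoptosis genes 0.529 (camera). Glutamate and GABA receptor genes had an adjusted p of 0.213 and voltage-gated channel genes 0.633. For neuron markers it was 0.970, with a test direction opposite in sign to the median of 0.01 and the mean of 0.04. With edgeR 1 neuron marker passed in each direction when adjusted over the list alone, Slc32a1, the vesicular transporter of inhibitory neurons, at 58.0 ± 3.97 and 76.3 ± 6.77 CPM, and Tubb3, a tubulin, at 493 ± 21.7 and 396 ± 32.1 CPM. For hypoxia response genes the mean of 0.04 and the median of −0.06 differed in sign, as did the mean of 0.01 and the median of −0.07 for oxidative stress genes.

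Markers of brain regions and of myelin varied between libraries of the same group. Hypothalamic and thalamic markers ranged from −1.20 to 1.63 in sham and from −1.06 to 1.74 in ischemia/reperfusion (score as above; camera, adjusted p = 0.626). Striatal markers ranged from −0.65 to 0.72 and from −0.34 to 1.43 (adjusted p = 0.317), and cortical markers from −0.07 to 0.05 and from −0.35 to 0.13 (adjusted p = 0.509). Choroid plexus markers were at −2.30 in ischemia/reperfusion replicate 2 and at −0.39 and 0.74 in the other ischemia/reperfusion libraries (adjusted p = 0.208). Myelin markers were at 1.07 in ischemia/reperfusion replicate 3 and at −0.42 and −0.03 in replicates 1 and 2 (adjusted p = 0.509). The first principal component of the 500 most variable rows held 32.3% of their variance and the second 27.8%. On the first, sham libraries lay from −16.5 to −9.30 and ischemia/reperfusion libraries at 25.7, 0.0130 and 15.0.

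Among lncRNAs, Meg3 and Mirg, imprinted genes of chromosome 12, and the nuclear RNAs Neat1 and Malat1 were higher in each ischemia/reperfusion library than in each sham library. Meg3, on chromosome 12 from 109540996 to 109571729 (mm10), had 644 ± 35.7 CPM in sham and 1075 ± 194 CPM in ischemia/reperfusion (SD, n = 3 each), a log2 fold change of 0.74 ± 0.13 (SE) with an adjusted p of 0.123 (edgeR). Mirg, from 109734981 to 109749457, had 10.9 ± 0.0573 and 19.9 ± 2.54 CPM. Neat1 had 45.6 ± 12.7 and 83.2 ± 9.26 CPM, and Malat1 5781 ± 713 and 7997 ± 557 CPM. Of 793 lncRNA genes tested, 0 were called by edgeR, 9 were called higher and 3 lower by DESeq2, and 104 had an unadjusted p under 0.05, 69 of them higher. Without ischemia/reperfusion replicate 1 edgeR called 17 higher and 7 lower.

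In the list of 22 lncRNAs studied in brain or stress, 6 passed with edgeR when adjusted over the list alone, namely Malat1, Neat1, Meg3, Snhg11, Kcnq1ot1 and Mirg, and 0 over all rows. DESeq2, over the rows it adjusted, called 4, Mirg, Meg3, Neat1 and Malat1. The list as a whole was not called (camera, adjusted p = 0.208). It was called by DESeq2 statistics (adjusted p = 0.00449) and with a mean of at least 1 CPM (adjusted p = 0.0485). Its adjusted p was 0.860 with an estimated correlation. The 5 lncRNA genes with the smallest edgeR p-values, none past the edgeR threshold, were Mirg, 6430411K18Rik, E030003E18Rik, Meg3 and B230323A14Rik, of which DESeq2 called all but the last. 6430411K18Rik had 6.62 ± 1.56 CPM in sham and 17.8 ± 4.23 CPM in ischemia/reperfusion (SD, n = 3 each), E030003E18Rik 11.8 ± 1.27 and 6.35 ± 0.925 CPM, and B230323A14Rik 0.908 ± 0.255 and 0.241 ± 0.0875 CPM. Rtl1 lies antisense to 6430411K18Rik, and no source used here states that counting used strand, so reads of the 2 genes cannot be separated. Inside single-exon genes, 231 clones on the same strand had a median of 1 times the gene's RPKM. The 2 clones on the opposite strand only had 0.798 and 2.61 times. Counting without strand would give such values, but 2 clones cannot settle it.

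**Figure D3:**
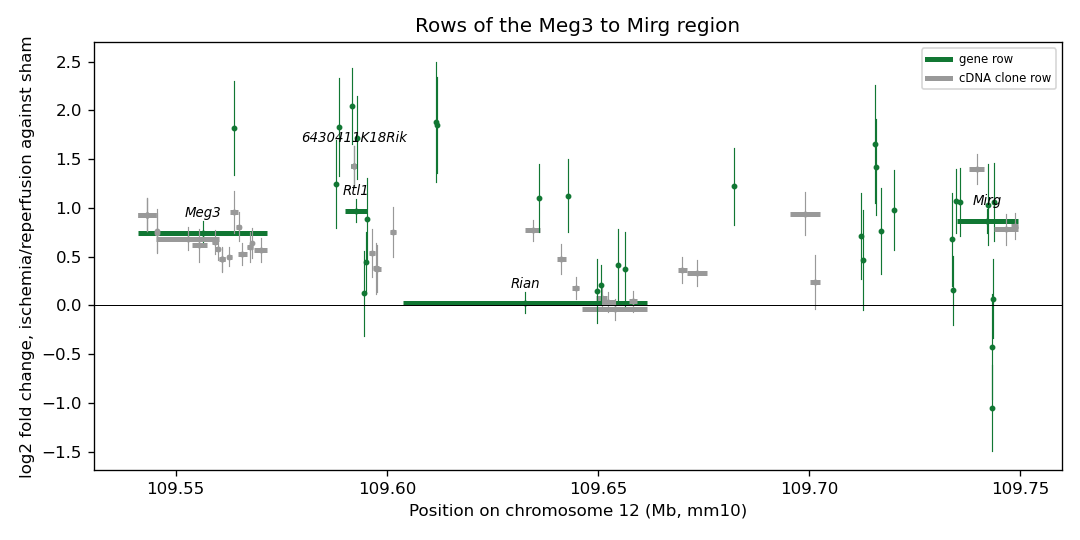
Log2 fold change of each tested row from Meg3 to Mirg against its position on chromosome 12 in Mb (mm10), with gene rows in green, cDNA clone rows in grey, row extent as a horizontal bar and the SE as a vertical line. Of 74 rows, 71 were positive, while the Rian row was at 0.03 and fantom3_9430047F21 within its span at 0.77.

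The authors' deposited table listed 11237 of 45851 rows with a q-value under 0.05, 6757 higher and 4480 lower after ischemia/reperfusion. With a log2 change of at least 1, the authors' deposited table listed 959 higher and 52 lower. Of its called rows, 11154 were tested here, and 1 was also called by edgeR, fantom3_5330411G14. An unadjusted edgeR p under 0.05 was found for 49.1% of these rows, which the authors' deposited table had selected on the same libraries. For Hspa1b the authors' deposited table gave a log2 fold change of 4.53 with a q-value of 1.2e-14.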

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

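Of the tests here, the fit on gene rows alone and edgeR without robust estimation were chosen only after the result was seen. Counts of called rows are given as higher and lower after ischemia/reperfusion, and values for gene lists are adjusted p-values of the list test; the cause of each move was not tested unless stated. The edgeR counts were 1 and 0 rows. They were 2 higher with upper-quartile factors and 4 higher both with limma-voom and without robust estimation, of which 2 were clone rows in each. With no low-count filter they were 51 and 26, of which 32 and 15 were clone rows and 3 and 1 lncRNA genes. With DESeq2 they were 355 and 229, of which 221 and 132 were clone rows and 9 and 3 lncRNA genes. With a mean of at least 1 CPM and with gene rows alone they were 0 higher, for gene rows alone because the called row was left out. Leaving out 1 library gave 0 to 650 higher and 0 to 407 lower rows, 0 to 420 and 0 to 250 clone rows, and 0 to 17 and 0 to 7 lncRNA genes; the highest values were without ischemia/reperfusion replicate 1. With RLE factors the counts did not change. The overlap with the authors' deposited table was 1 at both thresholds.

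With the replicate number as a block 0 rows were called higher, 0 of them clone rows, and the list of unfolded protein and integrated stress response genes had 0.0567. Same-numbered libraries had correlations of their deviations of −0.0678, 0.0337 and 0.110, and other pairs had −0.135 to 0.110. The numbers thus gave no sign of a pairing, but with so few libraries this check cannot exclude one. The block changed no other list call, and the log2 fold change of Kcne2 was −0.15 with it.

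The calls of 6 lists were lost with an estimated correlation, at 0.780 for immediate early genes, heat shock and chaperone genes, cytokine and chemokine genes, astrocyte markers and neutrophil and monocyte markers and 0.860 for unfolded protein and integrated stress response genes. With fry these were 0.281, 0.220, 0.277, 0.208, 0.281 and 0.522. Fry tests whether a list moves and not whether it differs from other rows. Other lists passed under some settings. The list of lncRNAs had 0.0485 with a mean of at least 1 CPM, 0.00449 with DESeq2, 0.0459 with limma-voom and 0.0205 with gene rows alone. Microglia markers had 0.0131 with DESeq2 and 0.0307 with gene rows alone, and NF-kB feedback genes 0.0177 with limma-voom and 0.0152 with gene rows alone. Each of these 3 lists had 0.860 with an estimated correlation.

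The direction of the test on neuron markers, not called under any setting, reversed at 0.896 with upper-quartile factors, 0.658 with a mean of at least 1 CPM, 0.788 with DESeq2, 0.925 with limma-voom, 0.484 with gene rows alone and 0.760 with fry. Voltage-gated channel genes, likewise not called, reversed at 0.942 with a mean of at least 1 CPM and 0.764 with gene rows alone. Kcne2 reversed to −0.33 with limma-voom.

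Leaving out 1 library gave these ranges of adjusted p for lists that changed side or direction. They were 3.6e-05 to 0.502 for NF-kB feedback genes, 4.4e-05 to 0.491 for choroid plexus markers, 0.170 to 0.914 for cortical markers, 0.0525 to 0.899 for erythroid markers, 0.00292 to 0.914 for glutamate and GABA receptor genes, 0.236 to 0.987 for hypothalamic and thalamic markers, 0.296 to 0.939 for hypoxia genes, 0.0339 to 0.543 for interferon genes, 0.00584 to 0.872 for microglia markers and 0.514 to 0.999 for neuron markers. They were 0.0199 to 0.987 for myelin markers, 0.0208 to 0.830 for oligodendrocyte precursor markers, 0.0674 to 0.797 for oxidative stress genes, 0.0753 to 0.999 for p53 target genes, 0.147 to 0.999 for pericyte markers, 0.00231 to 0.987 for reactive astrocyte genes, 0.0224 to 0.850 for striatal markers, 0.00014 to 0.219 for unfolded protein response genes and 0.203 to 0.999 for voltage-gated channel genes. Myelin markers changed direction past the threshold, at 0.0199 without ischemia/reperfusion replicate 3. Immediate early, heat shock, cytokine, neutrophil and astrocyte lists kept their call without any 1 library, with the preset correlation.

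Among 121 named genes, 14 changed sign under some setting, in each case uncalled in both fits. Leaving out 1 library gave log2 fold changes of −0.023 to 0.40 for Abcc9, −0.14 to 0.27 for Alas2, −0.19 to 0.62 for Foxj1, −0.030 to 0.65 for Hbb-bt, −1.01 to 0.90 for Kcne2, −0.022 to 0.56 for Kcnj8, −0.82 to 0.10 for Kl, −0.24 to 0.63 for Mag, −0.22 to 0.48 for Mobp, −0.0069 to 0.46 for Olig2, −0.34 to 7.13 for Oxt, −0.080 to 0.73 for Pde10a, −0.056 to 0.071 for Rian and −0.20 to 0.66 for Tac1. The depth of 45.4 to 49.7 (in units of 1e6 counts per library) leaves genes near the floor of 3 counts, such as Il1rn and Cxcl10 in sham, with wide errors.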

Other observations

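The tests on the divisions of the libraries by list and by DESeq2 were fixed before their results were seen. The other tests, those on called rows and unadjusted p by division, overlapping rows, the level of other windows of the genome, neurons, genomic DNA, host genes, unspliced RNA and the deposited p-values, were chosen only after the result was seen. Division of the 6 libraries into 3 and 3 is possible in 10 ways, too few for a share under 0.05. As many rows as the 1 called by edgeR were called in 2 of the 10, the real one included, with 1 as the highest other count. At an unadjusted p under 0.05 the real division gave 6281 rows and the highest other 2730, so 1 of the 10 reached the real count. With DESeq2 the real division gave 584 rows and the highest other 75, again 1 of the 10. For gene lists called by camera with the preset correlation the real division gave 6 and the highest other 15, and 8 of the 10 reached 6. The 10 divisions called 5 to 15 lists. The division with 15 set sham replicates 1 and 3 and ischemia/reperfusion replicate 2 against the others.

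Clone rows lying in a gene at under 0.1 of its RPKM, here called intron-like, were higher after ischemia/reperfusion, with a median log2 fold change of 0.37 over 6291 rows, 80.6% of them positive. Genomic DNA in the libraries is argued against, since clone rows in no gene over the same CPM range had a median of −0.0177, and of at most 0.12 in each of 3 CPM classes where intron-like rows had 0.28 to 0.44. Higher expression of the host genes is argued against, since their median log2 fold change was −0.03 and the median difference between clone and host was 0.383. A larger share of unspliced RNA after ischemia/reperfusion stays open. The median clone-to-host log2 ratio was taken on CPM, without correction for row length. It was −6.46 ± 0.04 in sham and −6.09 ± 0.07 in ischemia/reperfusion (SD, n = 3 each), a difference of 0.367 with each ischemia/reperfusion library above each sham library (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). This difference restates that clone rows were higher relative to their hosts and does not say why, and no test here separates transcription, splicing and the nuclear share of the RNA.

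From Meg3 to Mirg on chromosome 12, positions 109540996 to 109749457 (mm10), 71 of 74 tested rows had a positive log2 fold change, a region singled out because its values were high. Of 52 rows that share no position, 33 were positive with an unadjusted edgeR p under 0.05. This argues against counting of the same reads in overlapping rows as the only source. The 33 are not independent tests. Short neighbouring rows can share a read pair, and the region was picked for its high values. The median over 572 other windows of 300 kb was 0.0366 with an SD of 0.165, against 0.73 in the region. This argues against a general rise over rows of all kinds. These windows mix gene and clone rows. Intron-like clone rows had a median of 0.37, so a rise that the region shares with such rows stays open. The share of windows as high as the region was 0.524% and decides nothing, because the region was picked for its high values. A larger share of neurons is argued against, since the 13 neuron markers had a median log2 fold change of 0.00507 with an SD over members of 0.212. A change in the share of one neuron type stays open, as does a response of the locus to ischemia/reperfusion. The Rian row within the region was at 0.03 ± 0.11 (SE), but rows inside its span differed. Among them, fantom3_9430047F21 was at 0.77 and Mir1188 at 1.85, while fantom3_5530401N18 was at −0.04 and fantom3_C130082M19 at 0.04.

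The authors' deposited table called 11237 rows where edgeR called 1. The low-count filter is argued against as the cause, since 99.3% of those rows were tested here. P-values that carry counting error only are a candidate explanation, as the deposited p-values had a Spearman correlation of 0.999 across 40080 rows with a binomial test of the summed counts and of 0.802 with the edgeR p (rows are not independent replicates). The deposited p-values were larger than those of summed counts, with a median z of 0.577 times the binomial z, where a binomial test of group mean counts would give 0.577.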
